A study of Homo sapiens and Mus musculus with 21 samples.

How the data were processed

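Bulk RNA came from CUTLL1 cells that carried a lentiviral hairpin or were treated with ciclopirox; total RNA was extracted with Trizol, poly(A)+ libraries were made and read as 150 bp pairs on an Illumina instrument, per the labels' protocols. RIP used a DHX15 antibody or IgG with removal of ribosomal RNA, and single thymus cells were captured in 10x Genomics droplets, per the labels' protocols. FastQC 0.11.9, STAR 2.4.1.7 and 2.7.5c, DESeq2 1.32.0, DESeq, Cell Ranger 6.0.2 and Scanpy 1.7.1 and the builds hg19, hg38 and mm10 are listed without roles, per the submitters' processing notes. The strand setting of the counting and the time after infection or treatment are not given in the sources used here.

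The shRNA table holds RPKM values of 19848 genes in 9 libraries as deposited by the authors. All values were whole reads scaled by gene length and library total within a tolerance of 1e-05 reads, which recovered reads for 19748 genes (the other 100 were at 0) and library totals of 59702150 to 62633707 reads. The ciclopirox table holds a normalised signal for 23037 genes, which are gene counts divided by 1 size factor per library as deposited by the authors. In all 6 libraries 100% of values were whole multiples of 1 read within a tolerance of 0.01, giving 32451469 to 37177509 reads. The log2 fold change, p-value and adjusted p columns of that table are the authors' deposited values. Their p-value equals that of a chi-square with 2 degrees of freedom for 23034 of 23037 genes within a tolerance of 0.1% of the p-value, and for all within an absolute 1e-09, which is a test over 3 conditions, of which 2 have columns here. It calls 13848 genes at an adjusted p under 0.05, of which 3972 have a fold change under 1.96 of its standard errors, so it was not used as a test of ciclopirox. In the authors' deposited peak list each peak has a position, a strand, a fold enrichment ratio, a p-value, an FDR and a score; the score equals minus log2 of the FDR for all 4499 peaks, within a tolerance of 0.1%. The peak caller, the libraries it compared and whether they were pooled are not given in the sources used here. The thymus matrices hold whole UMI counts from Cell Ranger 6.0.1, per the file headers.

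Samples were grouped by the labels' titles and treatments. The groups, tests, alternatives, 27 gene lists, markers of 19 cell classes and the rule for named genes were fixed before the data were examined, except for 2 alternatives added later for the RIP comparison. RPKM values were tested as log2(RPKM + 1) with limma 3.58.1 (empirical Bayes with trend) in R 4.3.3 over all 9 libraries, on 15022 genes with an RPKM of at least 1 in at least 3 libraries. Ciclopirox values were tested as log2(normalised count + 1) with limma on 16825 genes with at least 10 in at least 3 of 6 libraries. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, two-sided. Lists with at least 5 measured members were tested with camera at a preset correlation of 0.01, adjusted over the lists, and again with an estimated correlation and with fry. Named genes were DHX15, the 12 rises and 12 falls called in both hairpins that ranked highest by the smaller of the 2 absolute log2 fold changes, with a mean of at least 1 RPKM, the 12 largest rises and falls with ciclopirox with a mean normalised count of at least 100, 6 further fixed genes, and up to 4 members of each list; in the thymus, up to 10 per direction and class. Some genes this rule takes are not reported here. edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 on the recovered reads served as alternatives and called 12327 and 12034 genes for the knockdown mean and 8181 and 8369 with ciclopirox.

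Counts were simulated at a dispersion of 0.01 with 200 genes changed. For 14765 genes of the knockdown comparison, 16% of those changed 1.25-fold, 91.5% of those changed 1.5-fold and 100% of those changed 2-fold were called. Of the unchanged genes 10 were called. For ciclopirox (16780 genes) the shares were 14%, 76% and 100%, with 9 unchanged genes called. For the thymus, 95.7% of intervals held the true ratio over 3063 genes in the DN2-3-like class. The simulated shares of called genes hold for that dispersion, and neither depth nor the number of libraries was varied. In the real shRNA libraries smaller changes were called, such as SLC7A6 at −0.15 log2 with shDHX15-2 (limma adjusted p = 0.00144). The shares therefore do not set the limits of the shRNA comparison. Counting intervals and floors of 3 counts cover counting error only. Libraries of a group differed by more than sampling noise, so all were counted.

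Peak positions were compared, without regard to strand, with RefSeq gene spans of GRCh38, since the header names no build. Gene spans contained 4150 of 4499 peaks, against 2801 to 3070 after shifting, and 107 peak edges lay within 2 bp of a gene edge against 0 to 3. Peak genes were compared with called genes by a two-sided Fisher's exact test over genes in both tables, and within 10 expression deciles with 10000 permutations.

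Thymus cells with at least 500 genes and under 10% mitochondrial UMIs were kept (8818 control and 7261 knockout; 5.78% and 12.8% of barcodes had 10% or more). Scrublet's own threshold marked 0 and 1 cells, so the cells with the highest scores were removed at an expected 0.8% per 1000 cells (622 and 422). Cells were scaled to 10000 UMIs and clustered with Scanpy 1.11.5 on 2000 variable genes, 30 principal components, 15 neighbours and Leiden resolution 1. Clusters were named from the fixed markers where at least 3 were detected with a mean log2 fold of at least 0.5. A cluster stayed unnamed where its leading genes held more markers of another class than of its best class. It also stayed unnamed where its cells were shallow and no marker was among its leading genes. The 5 classes with at least 50 cells in each library were compared within, as summed UMIs scaled to a total of 1000000 (CPM) with exact Poisson intervals. List medians were ranked among 10000 random lists of the same size matched over 20 expression bins. List members and random lists were taken from genes with at least 20 CPM in either library of the class. Genes ranked by size needed at least 50 CPM in either library. A gene low in 1 library could thus enter through the other. Other alternatives were pseudocounts of 0.1 and 10, other filters, median-centring, quantile normalisation, a replicate block, leaving out each library, a 2-fold minimum, Leiden resolutions of 0.5 and 2, looser cell filters, no doublet removal, thinning to 2000 UMIs and clustering without cell cycle genes or per library. Exon structures, sequences and the raw reads were not used here.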

Results

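The series addressed DHX15, a DEAH-box RNA helicase of pre-mRNA splicing and ribosome assembly, in acute leukemia and in the thymus. Its 21 samples came from CUTLL1, an established human T-cell acute lymphoblastic leukemia (T-ALL) line, and from mouse thymus. The shRNA experiment held 3 RNA-seq libraries each of CUTLL1 cells with a control hairpin against GFP (shGFP) and with the DHX15 hairpins shDHX15-1 and shDHX15-2. The library totals behind the RPKM values were 59702150 to 62633707 reads, over 99.7% of them in the listed genes. The drug experiment held 3 libraries with the solvent DMSO and 3 with 5 µM ciclopirox, an antifungal that chelates iron, with 32451469 to 37177509 reads counted in genes. RNA immunoprecipitation (RIP) from CUTLL1 comprised 2 libraries with a DHX15 antibody, 1 with IgG and 1 input, which were summarised by the authors as 1 peak list. Single-cell RNA-seq covered 1 thymus library of floxed control cells and 1 of Dhx15 knockout cells, from mice 6 weeks old, with 9434 and 8484 barcodes and medians of 3599 and 6084 UMIs per barcode. The labels do not state that replicates came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

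The hairpins asked which transcripts change in T-ALL cells when DHX15 is depleted. DHX15 RNA fell from 43.4 ± 0.649 RPKM (SD, n = 3) with shGFP to 17.0 ± 0.435 with shDHX15-1 and 16.5 ± 0.361 with shDHX15-2. EGR1, an immediate early transcription factor, fell from 93.2 ± 4.36 RPKM to 1.404 ± 0.202 and 1.43 ± 0.160. FOS, another immediate early factor, fell from 7.71 ± 0.124 to 0.264 ± 0.0258 and 0.165 ± 0.0126. DDIT4, an inhibitor of mTORC1 signalling, rose from 30.5 ± 0.289 RPKM to 272 ± 7.45 and 169.9 ± 0.828. On the log2(RPKM + 1) scale, which understates changes of low genes, DHX15 changed by −1.30 with shDHX15-1 and −1.34 with shDHX15-2 (SE 0.0255), and the mean of both by −1.32 (limma, Benjamini-Hochberg adjusted p = 5.69e-10).

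The 12 genes that fell with both hairpins and ranked highest by the smaller of the 2 absolute log2 fold changes included the MAP kinase phosphatase gene DUSP6, which fell from 7.11 ± 0.318 RPKM to 1.24 and 1.02. On the log2 scale DUSP2 changed by −1.63 with shDHX15-1 and −1.52 with shDHX15-2, the activation marker CD69 by −1.58 and −1.56, and IER2 by −1.45 and −1.28. The granzyme gene GZMA changed by −2.44 and −2.12. SCEL, its antisense SCEL-AS1, PI16 and SNORD12B completed the group with DHX15, EGR1 and FOS. SCEL and SCEL-AS1 overlap, and SNORD12B lies inside ZFAS1, so their reads may not be separable. The rises that ranked highest in the same way, beside DDIT4, were in KREMEN2 (3.09 and 2.83), a receptor for Dickkopf proteins, the adenylate kinase gene AK4 (2.76 and 2.26), the cathepsin gene CTSW (2.22 and 3.24), S100A10 (2.69 and 2.19), IGFBP2 (2.86 and 1.88) and the stress-induced repressor gene BHLHE40 (1.80 and 1.66). N4BP3, IGHV1OR15-1, TRAV41, SH3TC1 and CREB3L3 rose by 1.53 to 2.19, although IGHV1OR15-1 and TRAV41 belong to families of similar gene segments and are uncertain.

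MYC fell from 89.6 ± 0.483 RPKM with shGFP to 52.8 ± 0.738 and 54.4 ± 1.18, while NOTCH1, the receptor most often mutated in T-ALL, rose from 34.0 ± 0.620 to 53.1 and 43.0 (SD, n = 3). SLC7A5, a leucine transporter, fell from 87.5 ± 2.998 to 35.9 ± 0.275 and 42.0 ± 0.578 RPKM, and the glutamine transporter gene SLC1A5 from 57.5 ± 0.252 to 39.0 and 41.6. SLC7A6 fell from 15.5 ± 0.151 to 12.1 ± 0.312 and 13.9 ± 0.434 and SLC38A5 from 7.96 ± 0.215 to 5.90 ± 0.463 and 5.70 ± 0.197. These 2 transporter genes were chosen from knowledge of the study, so their fall, 2 of 2 over all genes tested and adjusted over the list alone, is not independent evidence.

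**Figure D1:**
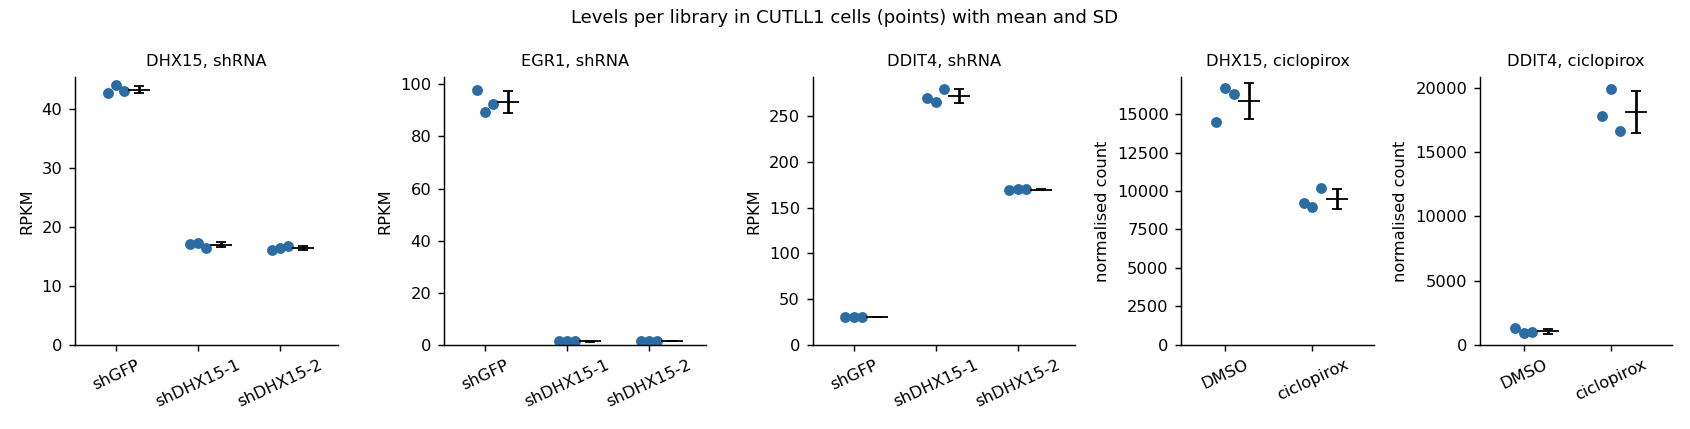
DHX15, EGR1 and DDIT4 in RPKM for the shGFP, shDHX15-1 and shDHX15-2 libraries, and DHX15 and DDIT4 in normalised counts for the DMSO and ciclopirox libraries. Points are libraries and bars show the mean ± SD of 3. DHX15 was lower in every knockdown library than in every shGFP library.

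Genes of ribosome biogenesis and of sterol synthesis fell almost throughout on knockdown, counting calls for the mean of both hairpins. Of 35 ribosome biogenesis genes 34 fell and none rose, with a median log2 fold change of −0.40 over both hairpins (camera, Benjamini-Hochberg adjusted p = 1.94e-14); LYAR changed by −1.07 with shDHX15-1 and −0.65 with shDHX15-2, and PNO1 by −1.10 and −0.58. Of 23 sterol synthesis genes 21 fell and none rose (median −0.52, camera adjusted p = 3.36e-10), among them INSIG1 (−1.65 and −0.93) and HMGCS1 (−0.88 and −0.64). Of 19 genes in the list of MYC and its common targets 16 fell and 2 rose (median −0.30, camera adjusted p = 2.53e-07), led by the spermidine synthase gene SRM (−2.16 and −0.53), while LDHA rose (0.48 with both). The heat shock and immediate early list had 15 falls and 2 rises among 20 (median −0.46, camera adjusted p = 2.53e-07), including the chaperone genes HSPH1 (−1.50 and −0.77) and HSPA8 (−1.45 and −0.30), with JUN rising (2.17 and 1.42). Of 48 spliceosomal helicase and core genes 30 fell and 10 rose (median −0.19, camera adjusted p = 6.54e-05), with EFTUD2, a core U5 protein gene, at −0.89 and −0.64 and DDX42 at 0.57 and 0.47. These 5 lists, and the hypoxia list, also passed with an estimated correlation between genes.

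Lists of energy, amino acid and iron genes also fell. Of 28 nuclear oxidative phosphorylation genes 22 fell and none rose (median −0.23, camera adjusted p = 1.22e-07; adjusted p = 0.0508 with an estimated correlation). Of 13 mitochondrially encoded genes 9 fell, MT-CYB by most among those named (−0.92 and −0.67), and 2 rose (median −0.32, camera adjusted p = 0.00194; adjusted p = 0.489 with an estimated correlation); this call ended after quantile normalisation (adjusted p = 0.327, range over alternatives 0.000111 to 0.327). Of 18 glutamine metabolism genes 13 fell and 3 rose (median −0.27, camera adjusted p = 0.00619; adjusted p = 0.0974 with an estimated correlation), with IDH1 at −0.79 and −1.18 and the glutamine synthetase gene GLUL at 0.91 and 0.51. Of 17 amino acid transporter genes 11 fell and 5 rose (median −0.20, camera adjusted p = 0.0166; adjusted p = 0.223 with an estimated correlation). With shDHX15-1 alone this list was not called (camera adjusted p = 0.0529), and with shDHX15-2 alone it was (camera adjusted p = 0.00118). Of 19 iron handling genes 11 fell, among them the iron exporter gene SLC40A1 (−0.93 and −1.08), and 6 rose (median −0.19, camera adjusted p = 0.0401; adjusted p = 0.174 with an estimated correlation), a call that ended after median-centring (adjusted p = 0.0713, range over alternatives 0.0343 to 0.0914), after quantile normalisation (adjusted p = 0.0914) and without shGFP replicate 2 (adjusted p = 0.0514). The iron handling call also ended with a replicate block, as given below. With shDHX15-2 alone the iron handling list was not called (camera adjusted p = 0.222), and with shDHX15-1 alone it was (camera adjusted p = 0.0432).

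Hypoxia response genes rose together. Of 28 members 27 rose and none fell, with a median of 0.70 (camera adjusted p = 2.72e-11), including VEGFA (2.03 and 1.35), the glycolytic gene ALDOC (1.88 and 1.44), the oxygen sensor gene EGLN3 (1.72 and 1.51) and P4HA1 (1.85 and 1.37). Of 26 interferon response genes 19 rose, IRF7 by 0.85 and 0.94, and 5 fell (median 0.23, camera adjusted p = 0.0383; adjusted p = 0.212 with an estimated correlation). Neither hairpin alone gave a call for this list (camera adjusted p = 0.0529 with shDHX15-1 and 0.135 with shDHX15-2). Several lists moved both ways without a call. In the list of stress response through ATF4 10 of 26 rose and 13 fell (camera adjusted p = 0.383), its median being −0.06 and its mean 0.10. Of 13 NOTCH1 target genes 8 rose, such as NOTCH3 (1.38 and 0.56), and 5 fell, such as HES1 (−0.93 and −1.40), with a camera adjusted p of 0.608. T cell identity genes divided into 13 rises, such as CD4 (1.09 and 0.48), and 13 falls, such as CD1A (−0.98 and −0.57), of 28 (camera adjusted p = 0.793, median 0.03, the test pointing down). G2 and mitosis genes (10 rose and 13 fell of 30, camera adjusted p = 0.278), S phase genes (13 and 10 of 31, adjusted p = 0.874), p53 targets (8 and 11 of 24, adjusted p = 0.413) and SR and hnRNP splicing regulators (16 and 16 of 35, adjusted p = 0.874, median 0.02, the test pointing down) were not called either. Of 3 measured markers of other cell types CD79A (0.49 and 1.23) and CD68 (1.15 and 0.65) rose and VIM (−0.94 and 0.12) fell for the mean of both hairpins.

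Over all 15022 genes tested, limma called 11162 with shDHX15-1 (6822 higher and 4340 lower, 382 by at least 2-fold) and 9870 with shDHX15-2 (5343 higher and 4527 lower, 181 by at least 2-fold). With the mean of both hairpins 10944 were called (6401 higher and 4543 lower), and 7389 were called with both in the same direction (4319 higher and 3070 lower), against 2426 and 1308 for independent lists. Fold changes of the hairpins correlated across genes (Pearson 0.755, covariance 0.107), where unchanged groups against the same 3 controls gave 0.498 and 0.00237, a same-sign share of 66.6% against the observed 77.6%, and 0.02 shared calls on average in 50 simulations. Genes are not independent replicates, and the 3 controls were not divided between the hairpins. Shared controls gave a covariance of at most 0.00267 in the simulations. A larger part from the shared controls, beyond the simulated spread, was not tested. Direct comparison of the hairpins called 9177 genes (3484 higher with shDHX15-2 and 5693 lower), and 821 genes were called in opposite directions. The threshold allows 1052 false calls over both hairpins, but a false call enters the 821 only if the other hairpin is called the other way. The 1052 therefore does not settle how many of the 821 are errors. The slope of shDHX15-2 on shDHX15-1 across genes was 0.606. The share of higher genes among those called depended on scaling, moving after median-centring from 61.1% to 46.0% with shDHX15-1, from 54.1% to 46.5% with shDHX15-2, from 58.5% to 46.2% for the mean, from 58.5% to 44.5% for both and from 38.0% to 54.1% between hairpins.

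**Figure D2:**
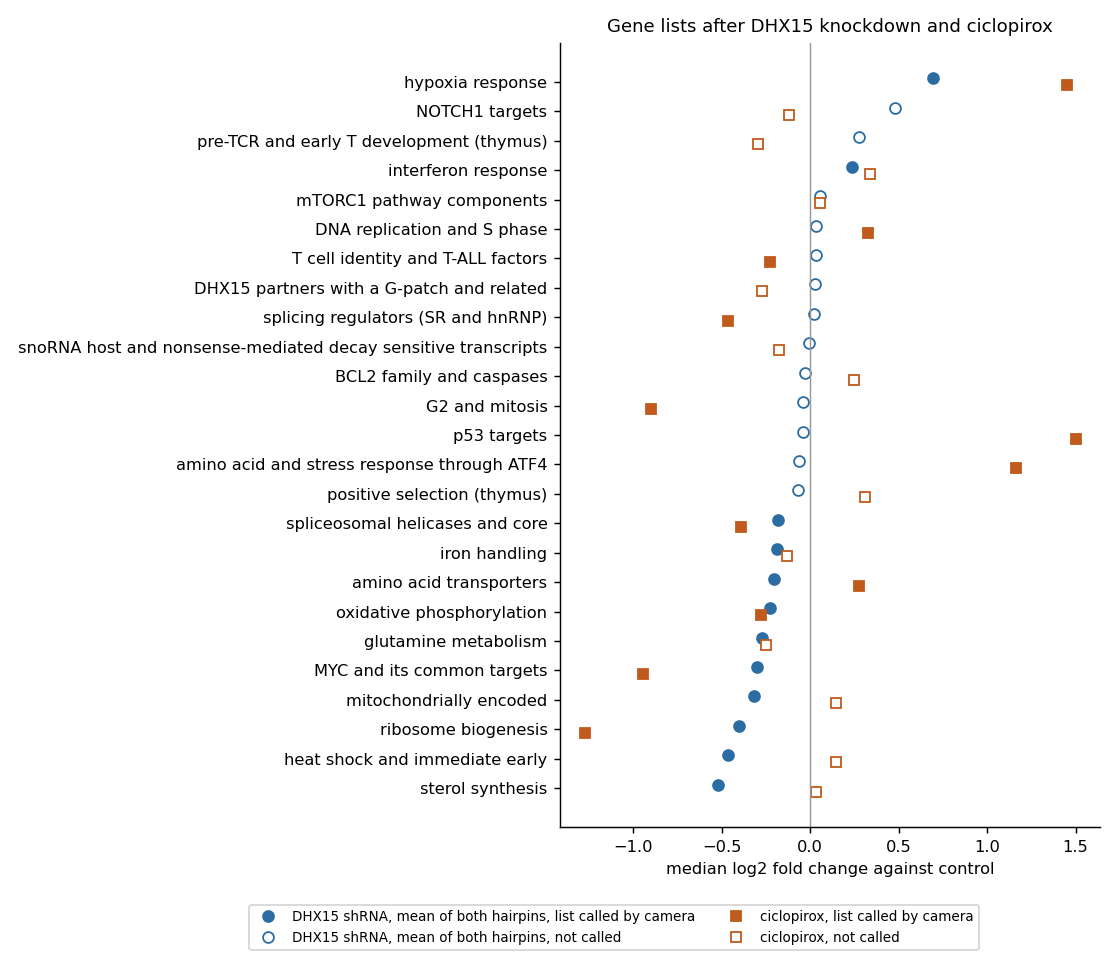
Median log2 fold change of 25 gene lists in CUTLL1, with circles for the mean of both DHX15 hairpins against shGFP and squares for ciclopirox against DMSO. Filled symbols were called by camera. Ribosome biogenesis lay at −0.40 and −1.28 and the hypoxia response at 0.70 and 1.45.

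RIP asked which transcripts DHX15 binds in CUTLL1 cells. The list held 4499 peaks, of which 3770 (83.8%) lay inside exactly 1 protein-coding gene, and the peaks named 2537 genes. PIEZO1 held 13 peaks, PKD1 11, TOP3B 11, DOT1L 10 and SRRM2, a splicing factor gene, 7, genes chosen after their values were seen. Among the fixed lists, 16 of 35 SR and hnRNP splicing regulator genes held a peak, where their expression deciles gave 6.79 expected (odds ratio 3.03, Fisher's exact p = 0.00158, Benjamini-Hochberg adjusted p = 0.0425). Of 31 mTORC1 pathway genes 13 held a peak, where the deciles gave 6.78 (odds ratio 2.60, Fisher's exact test, adjusted p = 0.189). These odds ratios and p-values were taken over all genes compared and do not allow for expression. SLC7A6 and SLC7A5 held peaks and SLC38A5 none.

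The strongest peak, with the authors' fold enrichment of 6.97 and FDR of 5.37e-182, lay in ANKRD42-DT on chromosome 11 from 83191130 to 83191455. The next lay in KIFC1, a mitotic kinesin gene, on chromosome 6 from 33391810 to 33391860 (fold 3.54, FDR 6.74e-77). Others among the top 10 lay in SEC31B (chromosome 10, 100516184 to 100519822, fold 2.46), CDK5R1 (chromosome 17, 32487656 to 32488006, fold 2.47), ARMH1 (chromosome 1, 44688270 to 44689109, fold 2.88) and HTRA2 (chromosome 2, 74529769 to 74529939, fold 2.71). Enrichment and FDR are the authors' values per peak; the median fold was 1.65, and 618 peaks (13.7%) reached 2. Positions are 1-based and follow GRCh38, whose genes contained 4150 peaks (92.2%) against 2801 to 3070 after shifting the peaks. Peaks were assigned to genes by position alone, so some may lie antisense to the gene named; gene strand and exon and intron annotation were not used here.

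Genes with a RIP peak were found more often among those higher after DHX15 knockdown and less often among those lower. Of 2188 peak genes in the 10027 genes compared, 801 (36.6%) were higher with both hairpins, against 30.8% of all genes compared (odds ratio 1.401, Fisher's exact p = 5.57e-11). Of the same genes 424 (19.4%) were lower with both, against 23.7% of all (odds ratio 0.724, Fisher's exact p = 4.68e-08). Their median log2 fold change was 0.10 against 0.02, and their median expression 7.82 against 8.37 RPKM. Within expression deciles the odds ratios were 1.38 and 0.745 (p = 0.0001 for each, the smallest that 10000 permutations can give). With a 2-fold minimum the ratio of the higher genes turned to 0.523 (47 genes, Fisher's exact p = 0.157), and that of the lower genes was 0.632 (20 genes, Fisher's exact p = 0.595).

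**Figure D3:**
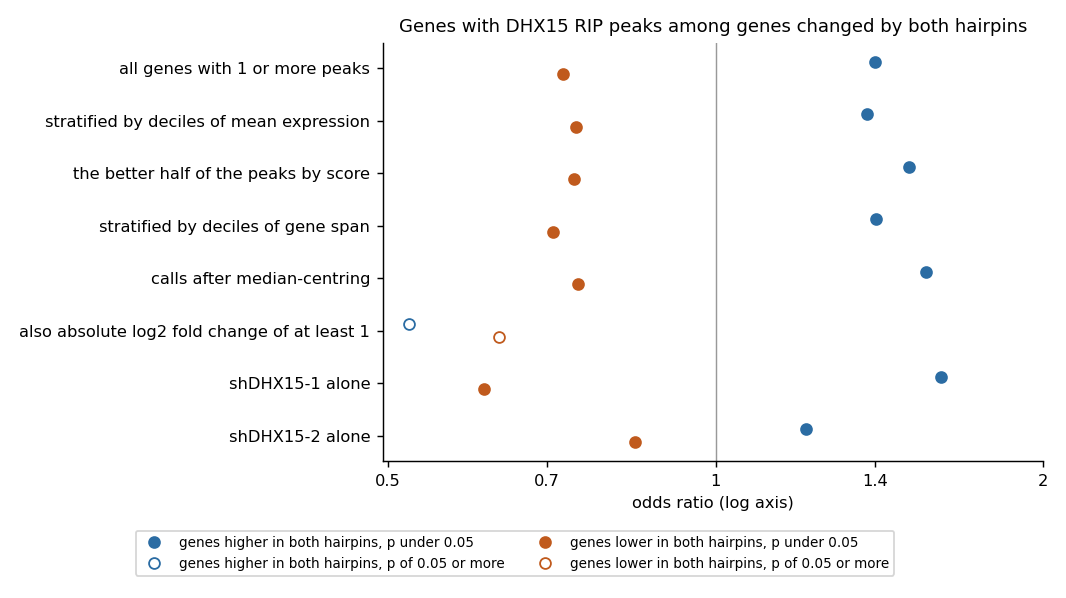
Odds ratios, on a log axis, of holding a RIP peak for genes higher (blue) or lower (orange) with both DHX15 hairpins, under 8 settings. Open symbols had p of at least 0.05, and the ratios of the main comparison were 1.401 and 0.724.

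Ciclopirox asked how the same T-ALL line responds to the drug. CDKN1A, a p53 target and cell cycle inhibitor, rose from 235 ± 26.1 normalised counts (SD, n = 3) with DMSO to 4385 ± 277, the cell death gene BBC3 from 22.8 ± 5.38 to 1996 ± 402, and DDIT4 from 1056 ± 186 to 18128 ± 1648. The DNA helicase gene PIF1 fell from 1198 ± 84.7 to 61.3 ± 14.2, and so did the mitotic genes CDC20 from 11076 ± 1933 to 1420.2 ± 81.1, PLK1 from 8217 ± 1289 to 1266 ± 216 and CCNB1 from 8586 ± 736 to 1673 ± 23.4.

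On the log2(normalised count + 1) scale JUN rose by 5.18, PPFIA4 by 5.09, the glycolysis regulator gene PFKFB4 by 4.43, APOBEC3H by 4.14, BMF by 3.87 and ATF3 by 3.82. DDIT4-AS1 rose by 4.13, but its reads may be those of DDIT4, which it overlaps. MYC changed by −2.33 (SE 0.0964, limma adjusted p = 8.41e-08) and MIR17HG, host of a microRNA cluster, by −2.41. HIST1H2BH (−3.16) and HIST1H2BK (−2.61) also fell but belong to a family of near-identical histone genes and are uncertain. DHX15 itself fell from 15832 ± 1171 to 9467 ± 661 normalised counts (log2 fold change −0.74, SE 0.0920, limma adjusted p = 8.7e-05; −0.74 in the authors' deposited table). SLC38A5 fell (−0.93), SLC7A5 (0.49) and SLC1A5 (0.62) rose, and SLC7A6 was not called (0.15, limma adjusted p = 0.203). NOTCH1 fell slightly (−0.24, limma adjusted p = 0.0314) but stood at 0.08 after quantile normalisation.

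All 34 measured ribosome biogenesis genes fell with ciclopirox, with a median of −1.28 (camera, Benjamini-Hochberg adjusted p = 5.07e-20), led by RRS1 (−2.28), DDX21 (−2.08) and WDR43 (−1.97). Of 24 p53 targets 23 rose and none fell (median 1.502, camera adjusted p = 9.1e-16), including BTG2 (3.73), PHLDA3 (3.44) and TP53INP1 (3.38). Hypoxia genes rose in 23 of 27 cases with 1 fall (median 1.45, camera adjusted p = 6.25e-14), such as BNIP3L (2.52), PFKFB3 (2.40) and VEGFA (2.00). G2 and mitosis genes fell in 24 of 30 cases with 1 rise (median −0.90, camera adjusted p = 7.61e-12). These 4 lists also passed with an estimated correlation. EDA2R and ADM, at 0 in all DMSO libraries, rose at least 11.2-fold and at least 36.5-fold over 3 reads per library, which left the p53 and hypoxia medians at 1.502 and 1.45.

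Further calls were lost with an estimated correlation. The ATF4 stress list had 23 rises and no fall among 27 genes (median 1.17, camera adjusted p = 7.82e-14; adjusted p = 0.0837 with an estimated correlation), led by CHAC1 (3.57) and JDP2 (3.21). The MYC list had 15 falls and 1 rise, of LDHA, among 16 genes (median −0.94, camera adjusted p = 1.09e-07; adjusted p = 0.104 with an estimated correlation). SR and hnRNP regulator genes fell in 21 of 34 cases with none rising (median −0.46, camera adjusted p = 4.94e-07; adjusted p = 0.0834 with an estimated correlation), and spliceosomal genes in 29 of 46 with 1 rise (median −0.39, camera adjusted p = 7.65e-07; adjusted p = 0.206 with an estimated correlation). S phase genes rose in 15 of 30 cases, CCNE1 and CCNE2 by 1.65 each, with 2 falls (camera adjusted p = 0.000413; adjusted p = 0.285 with an estimated correlation). Amino acid transporter genes rose in 9 of 19 cases, such as SLC6A9 (3.01), with 3 falls (camera adjusted p = 0.0033; adjusted p = 0.158 with an estimated correlation). Of 29 T cell identity genes 14 fell, RAG2 by most (−1.67), and 2 rose (median −0.23, camera adjusted p = 0.00501; adjusted p = 0.153 with an estimated correlation), a call that ended after quantile normalisation (adjusted p = 0.483, range over alternatives 0.00294 to 0.483). Of 25 oxidative phosphorylation genes 10 fell and none rose (median −0.28, camera adjusted p = 0.0017; adjusted p = 0.611 with an estimated correlation), and this call also ended after quantile normalisation (adjusted p = 0.213, range over alternatives 0.000327 to 0.213). Sterol synthesis (9 rose and 5 fell of 22, adjusted p = 0.641), interferon response (12 and 3 of 28, adjusted p = 0.0699), iron handling (5 and 6 of 18, adjusted p = 0.552) and NOTCH1 target genes (6 and 7 of 16, adjusted p = 0.713, median −0.12 and mean 0.26) were not called by camera.

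limma called 8157 of 16825 genes with ciclopirox, 3956 higher and 4201 lower, 2566 of them by at least 2-fold. Adjusted over the list alone, 34 ribosome biogenesis genes, 23 p53 targets, 25 hypoxia genes and 27 G2 and mitosis genes passed; on knockdown the numbers were 34 for ribosome biogenesis, 22 for sterol synthesis, 27 for hypoxia and 18 for the MYC list. DMSO replicate 1 stood apart from the other DMSO libraries on the second principal component (42.4 against −17.1 and −20.6; 12.1% of the variance). Without it 8986 genes were called, 7684 of them shared with the full set, and none of the 115 genes taken by the naming rule changed sign or call. The median log2 fold change over all genes tested with ciclopirox was −0.02, and −0.10 after median-centring, after which 40.1% of the called genes were higher in place of 48.5%.

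Knockdown and ciclopirox shared much of their direction. Across 10658 genes tested in both experiments fold changes correlated (Pearson 0.439, Spearman 0.456), with 1249 genes higher in both against 743 for independent lists and 1437 lower in both against 738. Of genes changed at least 2-fold in both, 35 went the same way, such as KREMEN2, DDIT4, AK4, BHLHE40 and VEGFA, and 3 the opposite way. The latter were EGR1 (1.92 with ciclopirox), FOS (3.44) and PI16 (1.27), which fell on knockdown. The experiments share no control library, and with shDHX15-2 alone the correlation was 0.305. Tables were normalised separately, so only fold changes were set side by side.

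The thymus libraries asked how thymocyte subsets differ without Dhx15. Resting double positive-like (DP-like) cells made up 58.7% of control cells (95% exact binomial interval 57.6 to 59.8) and 38.7% of knockout cells (37.5 to 39.8). DN2-3-like cells, the stage of T lineage commitment, made up 1.33% and 15.2%, 11.4 times the share in the knockout library (9.39 to 14.1), and cycling immature-like cells 8.19% and 17.9%. CD4 single positive-like cells made up 5.33% and 1.316%, and mature single positive-like cells 6.82% and 0.629%. Gamma delta-like T cells went from 0.427% to 4.26% and NK-like cells from 0.744% to 3.10%. The knockout share was 4.165 times the control share for NK-like, 3.08 for B-like, 4.23 for macrophage-like and 2.96 for neutrophil-like cells. Shares are relative, and cell numbers per thymus are not given in the sources used here. A higher share therefore need not mean more cells. With 1 library per group there is no test, and all thymus intervals cover counting error only. The control and knockout libraries held 8196 and 6839 cells after filtering, at medians of 3676 and 6901 UMIs, and 17.4% and 15.2% of cells stayed without a name. The unnamed clusters 2, 8 and 11 made up 6.92%, 8.96% and 1.57% of control cells and 0.731%, 3.04% and 11.45% of knockout cells. Markers placed cluster 2 nearest to DP-like and cluster 8 nearest to CD4 single positive-like cells. Their leading genes held more markers of another class, so the DP-like and CD4 single positive-like shares leave them out. Cluster 11 had the S phase genes E2f1 and Rfc3 among its leading genes, so the share of cycling immature-like cells leaves such cells out. Most DP-like cells lay in clusters 0 and 1 in the control library and in clusters 3 and 5 in the knockout library, and the DN2-3-like class held 109 control and 1041 knockout cells, so that a class may partly be its library. The knockout to control ratio of shares moved from 0.658 to 0.394 after thinning for DP-like cells, from 9.96 to 32.7 with looser cell filters for gamma delta-like cells and from 0.0922 to 0.651 with libraries clustered alone for mature cells.

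**Figure D4:**
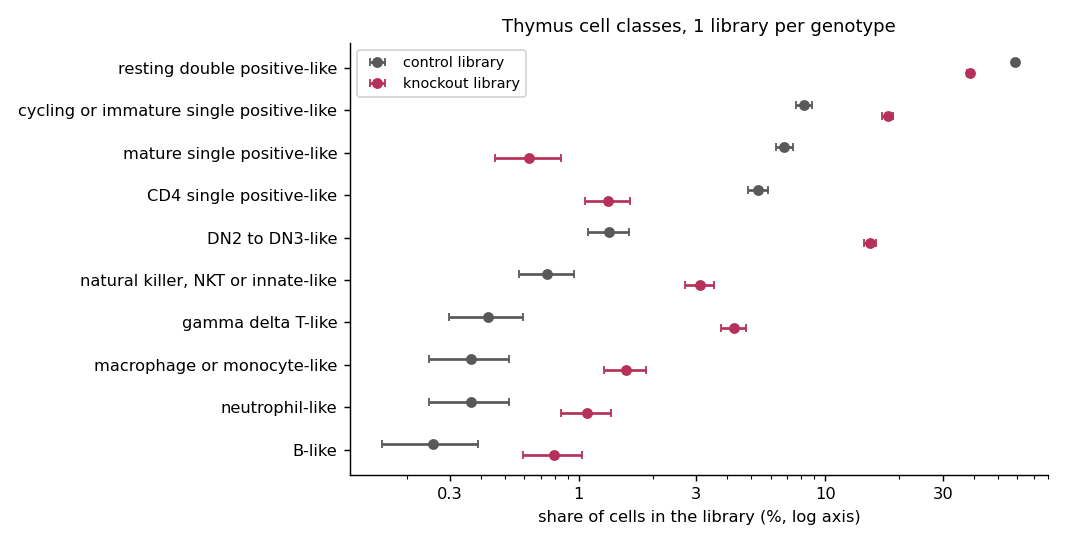
Share of cells per class in the control and knockout thymus library, on a log axis in percent. Bars are exact binomial 95% intervals and cover counting error only. DN2-3-like cells lay at 1.33% and 15.2% and DP-like cells at 58.7% and 38.7%.

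Dhx15 stood at 180.0 counts per summed 1000000 UMIs (CPM) in the control library (exact Poisson interval 176 to 184) and 101 in the knockout library (98.5 to 103). By class it was 173 and 112 in DP-like cells, 204 and 86.6 in cycling cells and 150.0 and 134 in DN2-3-like cells, a ratio of 0.895 (0.774 to 1.04) that was not distinguishable from 1 at this depth. The 3' tag may lie outside the floxed part, so these levels do not measure the deletion. In cells thinned to 2000 UMIs, which left out 530 and 268 cells, 29.1% and 18.9% had a Dhx15 UMI, against 50.0% and 51.5% without thinning.

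Interferon response genes were higher in immature knockout cells, though not in these alone. In DN2-3-like cells 16 of 19 members were higher with a median log2 ratio of 0.98, percentile 100 among 10000 random lists matched on expression, including Ddx60 (3.58 to 41.8 CPM), Ifi44 (5.01 to 47.4) and Irf7 (7.88 to 46.7). Members needed at least 20 CPM in either library. These genes, and Usp18 in DP-like cells, entered only through the knockout library. The control values of these DN2-3-like genes rest on few of 1395996 UMIs. Summed without that minimum, the whole list stood at 965 and 1789 CPM in DN2-3-like cells and at 393 and 728 in DP-like cells. In DP-like cells 8 of 9 were higher (median 0.76, percentile 100; 0.47 after thinning), such as Usp18 (4.06 to 29.6) and Bst2 (67.6 to 163). NK-like cells had 17 of 22 members higher (median 0.37, percentile 100), and the summed list went from 767 to 1880 CPM in gamma delta-like cells. In CD4 single positive-like cells the list went the other way, with 8 of 10 members lower (median −0.69, percentile 0). Mitochondrial genes took 4.201% of control and 5.13% of knockout UMIs in DN2-3-like cells, 3.83% and 4.84% in DP-like cells and 3.36% and 4.201% in CD4 single positive-like cells. DN2-3-like cells had lower ribosome biogenesis genes (28 of 31 lower, median −0.26, percentile 0), MYC list genes (18 of 20 lower, median −0.23, percentile 0.02), sterol synthesis genes (12 of 17 lower, median −0.28, percentile 0.12) and SR and hnRNP regulator genes (29 of 35 lower, median −0.17, percentile 0.05). DP-like cells had higher positive selection genes (7 of 7, median 0.64, percentile 100) and lower SR and hnRNP regulator genes (31 of 35 lower, median −0.32, percentile 0.02). The unnamed clusters 2 and 8 lie outside this class, at 6.92% and 8.96% of control and 0.731% and 3.04% of knockout cells. Cluster 8 had Nr4a1, Egr1 and Cd69 among its leading genes. The positive selection values thus cover the named class only and do not describe the whole library. NOTCH1 target genes were higher in DP-like cells (median 0.50) but lower after thinning (−0.24).

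Among single genes of DP-like cells, Zfp36l2, an mRNA decay factor gene, went from 105 to 909 CPM, the granzyme gene Gzma from 58.8 to 479, the peptide transporter gene Slc15a2 from 6.44 to 52.2 and Ifi27l2a from 21.4 to 129. The growth hormone gene Gh had no UMI in control DP-like cells and 102 CPM in knockout ones (96.8 to 108), at least 546-fold higher than a floor of 3 UMIs over the group. Insl5 went from 57.2 to 15.5, Dok2 from 85.9 to 26.4 and Tdrd5 from 172 to 55.9. In DN2-3-like cells Dqx1, a gene related to DEAH-box helicases, went from 3.58 to 93.0 (ratio 26.0, interval 11.1 to 80.2). Its 971 knockout UMIs lay in 110 of 1041 cells, up to 87 in 1 cell, and the shares of cells with a UMI overlapped (4.59%, 1.51 to 10.4, and 10.6%, 8.76 to 12.6). The interferon-induced gene Iigp1 went from 6.45 to 69.4 and Ifit1 from 13.6 to 60.8. The CD8 chain genes Cd8a and Cd8b1 went from 76.6 to 14.8 and from 88.1 to 19.1. Cox6a2 (55.9 to 5.84) and Tyrobp (98.9 to 12.6) rested on few control cells, 1 of which held 73 of the 78 Cox6a2 UMIs and 1 of which held 71 of the 138 Tyrobp UMIs.

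**Figure D5:**
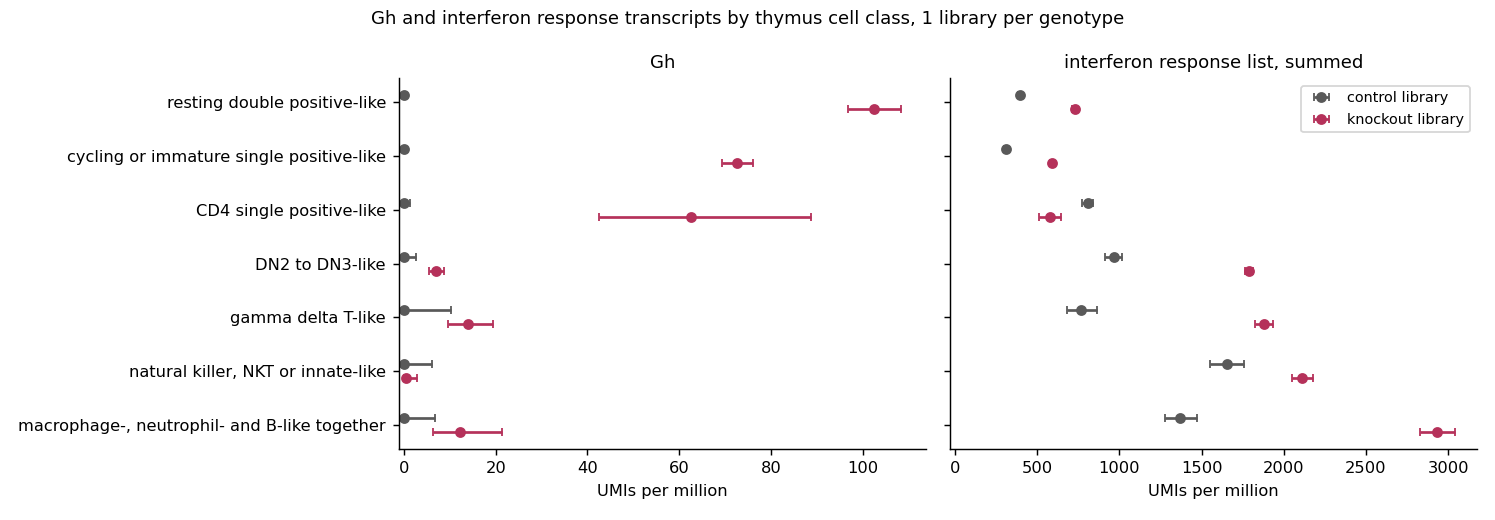
CPM of Gh and of the summed interferon response list by cell class in the control and knockout thymus library, with exact Poisson 95% intervals (counting error only). In DP-like cells Gh lay at 0 and 102 and the interferon list at 393 and 728.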

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

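The tests of scaling and of DHX15 loss reported here were chosen after the difference between the hairpins had been seen. The fold changes of the hairpins against shGFP differed for 9177 of 15022 genes by limma's test of the difference itself. Among named genes the difference (shDHX15-2 minus shDHX15-1, log2) was −1.66 for the kinesin gene CENPE, which stood at 0.26 with shDHX15-1 and −1.40 with shDHX15-2. It was −1.56 for HES4, which rose by 1.88 with shDHX15-1 and 0.33 with shDHX15-2, and 1.64 for SRM, which changed by −2.16 and −0.53. For CTSW, which rose with both hairpins, it was 1.02, and for VIM, at −0.94 with shDHX15-1 and 0.12 with shDHX15-2, it was 1.06.

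Scaling of the libraries as the whole cause is argued against by the 8886 genes that still differed after quantile normalisation, which gives all libraries one distribution. A deeper loss of DHX15 RNA with shDHX15-1 is argued against by DHX15 itself, which differed by −0.040 (SE 0.0255) between the hairpins and was not higher with shDHX15-2. Effects of either hairpin on other targets, and a difference in time or in DHX15 protein, stay open as untested candidates, and they may act together.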

How the results depend on the processing

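Calls after median-centring and within gene-span deciles for the RIP comparison were added after seeing the data; all other alternatives were planned. DHX15 on knockdown stayed between −1.46 and −1.27 under 8 alternatives and between −1.33 and −1.31 when each library was left out. Leaving out each library gave 10418 to 11058 genes for shDHX15-1, 9082 to 9712 for shDHX15-2, 10332 to 10690 for their mean, 6881 to 7076 for both, 8223 to 9216 between hairpins, 6319 to 8986 for ciclopirox, 11 to 12 knockdown lists and 12 to 12 ciclopirox lists. Other alternatives within 1.5 times ranged from 7691 to 12657, 7108 to 11168, 7602 to 12327, 5367 to 8317, 6620 to 10169 and 7077 to 8369 genes, and from 10 to 13 and 12 to 13 lists, in the same order. edgeR and DESeq2 on recovered reads shared 9764 of 12327 and 9481 of 12034 calls with limma for the knockdown mean, and 7867 of 8181 and 7922 of 8369 for ciclopirox. A 2-fold minimum left 382, 181, 196, 110, 67 and 2566 genes, fewer by construction. With an estimated correlation 6 knockdown and 4 ciclopirox lists were called; fry, which tests each list alone, called 25 and 19. The labels give no shared day for the shRNA replicate numbers, whose correlations were −0.0006 to 0.0951; a block moved the mean's calls from 10944 to 10858, and 7 of 9 libraries correlated best with their own number. The block also left the iron handling list without a call (camera adjusted p = 0.057, range over alternatives 0.0343 to 0.0914). No paired analysis was run for ciclopirox. Each column name gives a group and ends in a number, but not which labelled sample it is. Nothing in the sources used here says that equal numbers mark paired libraries, so they were not used as a block. Quantile normalisation turned NOTCH1 with ciclopirox to 0.084 and added 3 ciclopirox lists: BCL2 family (adjusted p = 0.0155, range 0.0155 to 0.121), positive selection (0.0407, 0.0407 to 0.134) and sterol synthesis (0.0238, 0.0238 to 0.819); the cause was not tested.

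RIP odds ratios stayed at 1.21 to 1.61 for higher and 0.613 to 0.843 for lower genes under 6 alternatives each; with a 2-fold minimum, which leaves few genes, they were 0.523 and 0.632. The knockdown and ciclopirox correlation was 0.452 to 0.4995 under 4 alternatives and 0.305 with shDHX15-2 alone.

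In the thymus, the knockout to control ratio of Dhx15 CPM moved from 0.560 to 0.615 after thinning. The DP-like share ratio moved from 0.658 to 0.613 (resolution 0.5), 0.394 (thinned), 0.434 (cell cycle genes left out) and 0.615 (libraries clustered alone), the cycling ratio from 2.19 to 1.89 (resolution 2), 1.77 (looser cell filter), 2.44 (no doublet removal) and 2.96 (alone), the gamma delta-like ratio to 32.7 (looser filter) and the mature ratio to 0.162 (cell cycle genes left out) and 0.651 (alone). Reversed log2 ratios were as follows. Ccl4 in NK-like cells (−2.63 at resolution 1) stood at 1.22 (resolutions 0.5 and 2, cell cycle genes left out), 1.249 (looser filter), 1.05 (no doublet removal) and 1.31 (alone), and Ccl3 (−2.43) at 3.02, 3.06, 2.86 and 3.114; 1 control cell held 163 of 174 Ccl4 and 70 of 71 Ccl3 UMIs. Positive selection genes in NK-like cells (−0.54) stood at 0.00966 (resolutions 0.5 and 2, cell cycle genes left out). Cox6a2 in DN2-3-like cells stood at 0.77 (resolution 2), 0.70 (no doublet removal) and 0.75 (cell cycle genes left out), and S phase genes in cycling cells (0.06) at −0.0092 (resolution 2) and −0.11 (looser filter). Thinning turned NOTCH1 targets (−0.028), hypoxia genes (−0.29) and Tyrobp (0.02) in DN2-3-like cells and NOTCH1 targets in DP-like cells (−0.24; −0.19 with cell cycle genes left out). The cause was not tested for these changes. CD4 single positive-like cells got no name, and so no value, at resolution 0.5, after thinning, with no doublet removal, with cell cycle genes left out and alone, nor did DN2-3-like and gamma delta-like cells alone. The number of cells limits the thymus values, since a class with under 50 cells in a library was not compared within.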

Other observations

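All tests of explanations reported in this part were chosen after the patterns had been seen, as were the counts of other sample splits. In the knockout thymus library, cycling immature-like cells had lower G2 and mitosis genes (30 of 30 members lower, median log2 ratio −0.49, percentile 0 among random lists) and higher ribosome biogenesis genes (28 of 32 higher, median 0.34, percentile 100) and MYC list genes (20 of 20 higher, median 0.25, percentile 100). The class pools clusters 6, 12 and 16, with 267, 235 and 169 control and 227, 763 and 235 knockout cells, and its values were not separated by cluster. Ribosomal protein genes took 21.6% of the UMIs of control and 26.6% of those of knockout cycling cells, and 14.7% and 21.7% in DP-like cells. Mitochondrial genes took 2.76% and 3.41% in cycling cells. The interleukin receptor gene Il2ra, of the DN2-3 stage, went from 29.9 to 103 CPM in cycling cells, while Ccr9 went from 277 to 96.0 and Cd4 from 148 to 54.0, genes of later stages. In CD4 single positive-like cells Gpr83 (99.3 to 10.1) and Ikzf2 (95.6 to 26.2), genes of regulatory T cells, were lower. Myo6 went from 18.6 to 649 there, on 322 UMIs in 22 of 90 knockout cells.

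In CUTLL1 cells the knockdown moved death regulators both ways. Of 20 genes of the BCL2 family and caspases 9 rose, including the BH3-only genes BCL2L11 (1.08 with shDHX15-1 and 1.17 with shDHX15-2) and BMF (1.00 and 0.58), and 10 fell, including CYCS (−0.88 and −0.69) and PMAIP1 (−0.79 and −0.73), with a camera adjusted p of 0.489. The splicing kinase genes CLK1 (1.02 and 0.85) and CLK4 (0.86 and 0.74) rose. Of 23 genes of G-patch and related partners of DHX15 9 rose, such as RBM5 (0.75 and 0.49), and 6 fell, such as GPATCH4 (−1.05 and −0.39; camera adjusted p = 0.874, the median of 0.02 turning to −0.05 after median-centring). The snoRNA host genes SNHG3 (−1.52 and −1.11) and DANCR (−1.38 and −1.01) fell, in a list with 8 rises and 8 falls among 22 genes (camera adjusted p = 0.655).

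Interferon response genes stood higher in most classes of the knockout thymus library. In CD4 single positive-like cells the summed list changed by −232 CPM while it gained 824 in DN2-3-like cells. This argues against free RNA in the droplets as the whole cause only if the class holds like cells in both libraries. That was not shown, since it had 437 control and 90 knockout cells and got no name under several alternatives. In control cells the list stood at 393 CPM in DP-like, 807 in CD4 single positive-like and 1906 in mature single positive-like cells, so a change of mix could lower it. Higher depth per knockout cell is argued against in DN2-3-like cells, which held 0.783 times the UMIs of control cells on average (10026 against 12807), but stays open in DP-like cells, which held 1.38 times as many and whose median log2 ratio went from 0.76 to 0.47 after thinning. A response of the whole organ is a candidate explanation, since macrophage-, neutrophil- and B-like cells together had 2.14 times the level of the control. The rise was carried by neutrophil-like (1773 to 4214 CPM) and macrophage-like cells (1041 to 2244). It was not carried by B-like cells, whose intervals overlapped (867, 742 to 1007, and 1092, 969 to 1226). These classes were small, with 30 control and 74 knockout neutrophil-like cells and 30 and 106 macrophage-like cells. The neutrophil-like cluster had 2 markers of another class among its leading genes, which included H2-Eb1, H2-Aa and H2-Ab1. Its rise may therefore be a change of mix. The deleted cells themselves may be the source of such a response. With 1 library per group a difference between animals or preparations cannot be told apart from the knockout.

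Gh transcripts appeared in 2267 of 6839 knockout cells (33.1%) and in 0 of 8196 control cells, which allows a share of cells with a UMI, though not of cells expressing the gene, of up to 0.0366%. Over all cells the knockout level of 60.4 CPM was at least 926-fold higher than the floor of 3 UMIs over the control group, while the related pituitary gene Prl, chosen after its values were seen, had 0 UMIs in both libraries. Free RNA as the whole cause is argued against by the level in DP-like cells, 8.40 times that of macrophage-, neutrophil- and B-like cells together (12.2, interval 6.30 to 21.3; 4.27% of 234 cells with a UMI, at a median of 2926 UMIs per cell). Of 6 T lineage classes 3 lay above that upper bound, DP-like (102), cycling (72.6) and CD4 single positive-like cells (62.5, 42.5 to 88.7), while gamma delta-like (14.0, 9.72 to 19.4), mature single positive-like (10.8, 2.22 to 31.5) and DN2-3-like cells (6.99, 5.48 to 8.79) overlapped that interval, the last lying above NK-like cells (0.522, 0.0132 to 2.91, on 1 UMI in 212 cells). A transgene active in T lineage cells that carries growth hormone sequence, as some Cre lines do, stays open as a hypothesis that these 3 of 6 classes do not decide; the labels name no such line, and it was not tested by sequence.

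Other splits of the same libraries were counted for each result across genes. The real split of the mean of both hairpins against shGFP was the 1 of 100 splits with as many genes (10944; highest other 7524), likewise for genes called with both hairpins (1 of 100; 7389 and 5418). The other splits mix groups that differ, so their counts still hold group differences. Libraries of a group may also be technical replicates. These ranks show that the counts depend on the labelled groups and do not exclude chance between cultures. For gene lists the real split was also 1 of 100 (12 and 11), but the gap of 1 list lies within the range of 11 to 12 given by leaving out single libraries, so this is not read as an exclusion either. For shDHX15-1 (11162; highest other 0), shDHX15-2 (9870 and 0), the hairpins against each other (9177 and 1), ciclopirox (8157 and 0) and ciclopirox gene lists (12 and 12, in 3 of the splits), 10 splits are too few for a share under 0.05.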
